A study of Danio rerio with 6 samples.

How the data were processed

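The series holds 6 bulk RNA sequencing libraries from dissected zebrafish guts, 3 labelled as transected wild type and 3 labelled as wild type. Per the labels, each library pooled 10 to 15 guts, RNA was purified with a single-cell RNA kit, stranded mRNA libraries were prepared with TruSeq reagents and sequenced as 100 bp paired-end reads on a NovaSeq 6000, and reads were checked with FastQC 0.11.8 and aligned to the danRer11 genome. The deposited table holds raw counts per gene symbol, whole numbers with a different total in each library and no normalization by the authors. The aligner, the counting tool and the gene annotation are not given in the sources used here. fabp2, an abundant gene of enterocytes, had 3 to 11 counts per library, so a low or missing value in the table may reflect how genes were annotated or counted, and duplicated genes were not examined for shared reads. Raw reads were not used here. Gene symbols and neighbouring genes were looked up in a RefSeq table of another assembly, GRCz12tu, so no coordinates are given. Of 15419 symbols, 15329 were found in a reference table of names.

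Groups were taken from the sample labels. Both groups carry replicate numbers 1 to 3, and the data were used to see whether the numbers pair the libraries. Each library's deviation from the mean of its own group was correlated between groups over 11466 genes, which are not independent of each other. Pearson's r was 0.450, 0.512 and 0.177 for libraries with the same number, and each library correlated most with the one of its own number. Pair 3 was the weakest, with 0.177 against 0.118 for transected replicate 2 with control replicate 3. A blocked alternative, fixed in advance, used the numbers as pairs. Counts of libraries within a group differed by far more than counting error (chi-square per degree of freedom 26.4 to 243), so none are copies of each other.

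Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), scaled with TMM (factors 0.935 to 1.05) and fitted with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with robust dispersion and group as the only term. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. CPM values use the TMM-scaled library sizes. The standard error of a log2 fold change is the fold change divided by the root of the F statistic. For il22, il26 and lepb, ratios of counts carry 95% intervals where these are given, which cover counting error only, and il22 and il26 were compared by exact two-sided permutation tests. One count is worth about 0.0398 to 0.0465 CPM before scaling, so a gene with 0 counts could hold up to 0.119 to 0.139 CPM (3 counts).

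Before the data were examined, 35 gene lists were written down for the gut's cell types, neighbouring tissues, immune and stress responses and metabolism. The comparison, the tests and the rule for named genes were written down with them. List members were matched to symbols without regard to case or through a table of synonyms. Over all lists 1199 different genes were found in this way, and members not found were left out. Of 26 goblet cell markers 12 were found, and of 15 BEST4/OTOP2 cell markers 7. After matching, 3 synonyms were set aside because each belongs to a different gene. A list was tested if at least 5 members passed the filter, which all 35 did. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and adjustment over the 35 lists, and again with a correlation estimated per list and with fry. Members were also adjusted over the list alone. The rule named il22 and il26, up to 6 genes per direction past the threshold with an approved-style symbol, an average log2 CPM of at least 1 and non-overlapping groups, and 2 members past the threshold in each of the 12 lists with the smallest camera p. It returned plekhs1, il22 and il26, since few genes passed. All other genes named were singled out after their values were seen, mostly because they passed when adjusted over the list alone or in DESeq2.

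Alternatives fixed in advance were DESeq2 size factors, upper-quartile and library-size scaling, no filter, a filter of CPM at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, robust fitting off, the replicate block, leaving out each library in turn, an adjusted p under 0.01, a fold change of at least 2 and a test against a 1.5-fold change. Added after the data were seen were DESeq2 with the block, fits without the replicate 1 libraries of both groups, and the list tests with both the block and an estimated correlation or fry. The scalings moved the median log2 fold change of all genes by at most 0.0101. The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold between groups of 3. There edgeR recovered 43% and 91% with 5 false calls, DESeq2 63% and 98% with 40 false calls, and limma-voom 40% and 91% with 5 false calls. Simulated counts were drawn independently for each gene, without the replicate pairs or the correlation between genes of the real libraries. The changed genes had an average log2 CPM of at least 1. The shares recovered and the false calls therefore need not hold for the real comparison.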

Results

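RNA was sequenced from dissected guts of wild-type zebrafish larvae (Danio rerio). The labels give 5 days post-fertilization without saying whether this is the age at transection or at collection. Each of the 6 libraries pooled 10 to 15 guts. In 3 libraries the gut had been transected across the whole organ 24 h before collection, and these are called transected here. The other 3 libraries carry no mention of transection in their labels and are taken here as uncut controls. Total counts were 25131242, 21525093 and 24498862 in transected replicates 1, 2 and 3, and 23624582, 23007422 and 21835608 in control replicates 1, 2 and 3. Between 12838 and 13140 genes had at least 1 count in a library, and the 10 most abundant genes took 13.7% to 18.9% of a library's counts. The first principal component held 47.0% of the variance. On it the replicate 1 libraries of both groups stood apart from the other 4 libraries, at 33.1 (transected) and 44.3 (control). Control replicate 2 lay far out at the other end, at -48.5, with the remaining libraries from -15.5 to -0.00368. The second component held 23.6% and separated the groups, with the transected libraries at 8.72 to 29.5 and the controls at -17.8 to -23.8.

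The comparison of transected with control guts asks which genes differ 1 day after the organ is severed, and in particular where the cytokines il22 and il26, named in the study's title, stand at that time. Transected guts held far more of a few transcripts that control guts barely held. plekhs1, which encodes a protein with a pleckstrin homology domain, rose from 0.270 ± 0.157 CPM (counts scaled to a common library size) in controls to 14.9 ± 3.27 CPM (mean ± SD, n = 3 libraries per group here and below). Its log2 fold change was 5.73 (SE 0.38), with an edgeR adjusted p of 0.0301. The uncharacterised locus LOC100535095, a long non-coding RNA in the RefSeq table, rose from 0.495 ± 0.0807 to 31.5 ± 13.6 CPM, a log2 fold change of 5.97 (SE 0.43, adjusted p = 0.0305). Both were higher in all 3 transected libraries than in any control. Across the alternatives run, plekhs1 kept a log2 fold change of 5.43 to 6.40 and passed in 12 of 18, with adjusted p from 3.46e-35 to 0.437, and LOC100535095 lay between 5.62 and 6.25 and passed in 11 of 18, with adjusted p from 1.07e-45 to 0.437.

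In edgeR these 2 genes were the whole set past an adjusted p of 0.05 among 11466 genes tested, with 2 higher and 0 lower. At an unadjusted p under 0.05 there were 495 higher and 407 lower genes, where 573.3 over both directions together would be reached by chance. The 3 transected libraries lay wholly above the 3 controls for 858 genes and wholly below for 731, together 13.9% of genes against 10% by chance. DESeq2 called 92 genes higher and 60 lower, and the 152 had the same sign and an unadjusted p under 0.05 in edgeR, while a regrouping of transected replicate 1 with control replicates 1 and 3 against the rest gave 262 in DESeq2. With limma-voom 0 genes passed in either direction. The counts moved with single libraries: edgeR called 0 genes higher without transected replicate 1, transected replicate 3, control replicate 2 or control replicate 3, 1 without transected replicate 2 (LOC100535095), and 4 higher (plekhs1 among them) with 1 lower without control replicate 1. Without the replicate 1 libraries of both groups, edgeR called 99 genes higher and 172 lower. Of these 271 genes, 263 had the same sign with all 6 libraries, a set that includes the libraries used for the calls. With all 6, 162 had an unadjusted p under 0.05 in edgeR and 82 passed in DESeq2. With the replicate number as a block, edgeR called 3 genes higher (plekhs1, LOC100535095 and si:ch211-153b23.4) and 1 lower (cyp2k6), each at an adjusted p of 0.0495, and DESeq2 called 159 higher and 123 lower.

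il22, a cytokine of the IL-10 family that acts on epithelia, was higher in all 3 transected libraries than in any control, at 3.23 ± 1.59 against 1.03 ± 0.454 CPM. The libraries held 41, 105 and 78 il22 counts in transected guts and 13, 25 and 31 in controls, a ratio of 3.0, 4.07 and 2.40 in pairs 1, 2 and 3. The log2 fold change was 1.64 (SE 0.52), and the difference did not pass over all genes in edgeR (adjusted p = 0.515). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. Of the 18 alternatives, 2 gave an il22 call: DESeq2 with the replicate block (log2 fold change 1.61, adjusted p = 0.0151) and DESeq2 without the replicate 1 libraries (1.64, adjusted p = 0.00840), over a range of 0.00840 to 0.997. In edgeR with the block the log2 fold change was 1.62 (adjusted p = 0.179). il22 was lower in the replicate 1 libraries than in the rest of their own group, by a log2 CPM of -1.30 in transected and -1.16 in control guts.

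il26, the related cytokine, was near the detection limit and below the expression filter, with 7, 4 and 2 counts in transected guts and 1, 1 and 0 in controls. The mean was 0.179 ± 0.0914 against 0.0290 ± 0.0253 CPM. The ratio of 6.22 has a 95% interval of 1.41 to 56.8 from counting error alone, and the exact two-sided permutation p was again 0.1. il10 had 4 counts in transected and 5 in control guts. Among the receptors and signalling genes of these cytokines, socs3a, the feedback inhibitor of JAK-STAT signalling, was 159 ± 40.6 CPM in transected guts and 46.4 ± 7.57 in controls, and rose when adjusted over the list alone (adjusted p = 0.00141, log2 fold change 1.78, SE 0.22), though not over all genes (0.122 in edgeR, 5.5e-10 in DESeq2, range over the alternatives 2.25e-23 to 0.713). stat3 was 116 ± 43.1 against 70.22 ± 18.2 CPM, with overlapping groups (adjusted p = 0.683 in edgeR, 0.586 in DESeq2). jak1 was 86.3 ± 8.24 against 69.1 ± 1.51 CPM (0.511 in edgeR, 0.489 in DESeq2). Of the 18 alternatives, 3 called stat3 and 1 called jak1. The IL-10 family cytokine axis rose as a list (camera adjusted p = 0.000187, 0.140 with an estimated correlation): 11 of 12 tested members had a positive log2 fold change, with a median of 0.62. When adjusted over the list alone 1 member rose, against 5 with the replicate block and 6 without both replicate 1 libraries.

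**Figure D1:**
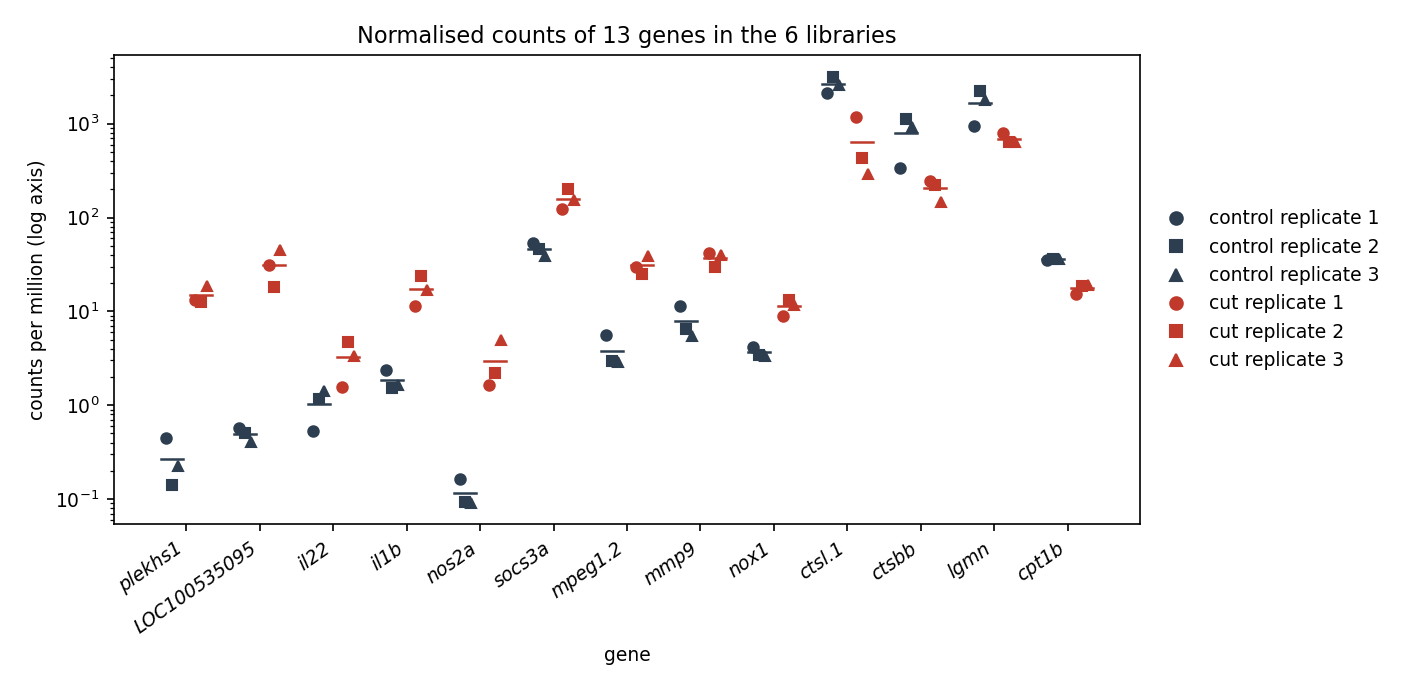
Normalised counts (CPM, log axis) of 13 genes in each of the 6 libraries, with symbols for replicate number, colours for group and short lines for the mean of 3 libraries. For each gene plotted the 3 transected libraries lie wholly above or wholly below the 3 controls, and plekhs1 averages 14.9 CPM in transected guts against 0.270 CPM in controls.

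Gene lists fixed in advance gave a broader picture. Of 35 lists, 13 rose and 5 fell by the camera test with a preset inter-gene correlation of 0.01. With an estimated correlation 0 lists passed in either direction, and that test's adjusted p is given beside each call. The self-contained fry test, which asks whether a list's genes move on balance one way, called 3: inflammatory mediators up (adjusted p = 0.000752), macrophage markers up (0.0320) and enterocyte lipid handling down (0.00624). With the replicate block, camera called 13 lists up and 6 down, and fry and the estimated correlation called 0. Over all genes tested, edgeR called 0 of the 1025 list members tested, against 99 higher and 37 lower at an unadjusted p under 0.05 and 27 and 8 in DESeq2. When adjusted over the list alone, 24 members rose and 13 fell. The members named below were chosen after their values were seen.

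Inflammatory mediators rose as a list in transected guts. il1b, the pro-inflammatory cytokine interleukin-1 beta, stood at 17.3 ± 6.16 against 1.84 ± 0.443 CPM. The nitric oxide synthase gene nos2a stood at 2.95 ± 1.79 against 0.115 ± 0.0404 CPM, and the NF-kB inhibitors nfkbiaa and nfkbiab, which NF-kB itself induces, at 56.1 ± 12.7 against 28.2 ± 2.37 and 102 ± 12.7 against 61.7 ± 3.31 CPM. lepb, a leptin gene induced in regenerating zebrafish tissue, had 11, 84 and 38 counts in transected guts and 0, 1 and 2 in controls, a ratio of 42.4 (95% interval 14.2 to 208.3, counting error alone). Of 23 inflammatory mediators tested, 20 had a positive log2 fold change, with a median of 0.72. Over all genes tested 0 members passed in edgeR, and 6 were higher in DESeq2. When adjusted over the list alone 6 rose in edgeR: il1b (0.000884), nos2a (0.00205), nfkbiab (0.00467), the chemokine cxcl18b (0.00517), nfkbiaa (0.00592) and lepb (0.0116). The list rose by camera (adjusted p = 4.5e-09, 0.0801 with an estimated correlation). Each transected library lay above each control in its median level, at 0.43, 0.30 and 0.20 against -0.36, -0.32 and -0.31 (log2 CPM relative to the mean of the 6 libraries).

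Macrophage markers rose as well (camera adjusted p = 5.22e-07, 0.140 with an estimated correlation), with 11 of 14 tested members positive and a median log2 fold change of 0.64. mpeg1.2, a perforin-2 gene of macrophages, was 31 ± 7.03 CPM in transected guts and 3.80 ± 1.58 in controls. It rose when adjusted over the list alone (0.000852), as did spi1a and spi1b (0.00383 each), which encode the myeloid transcription factor PU.1. So did mfap4 (0.0201), lcp1 (0.0265) and the CSF1 receptor gene csf1ra (0.0282). These were 6 members, against 0 over all genes tested in edgeR and 4 in DESeq2. Neutrophil markers rose as a list (camera adjusted p = 0.00146, 0.522 with an estimated correlation), with 7 of 10 members positive and a median of 0.85, and 0 members passed in edgeR, alone or over all genes (4 higher at an unadjusted p under 0.05, 0 in DESeq2). Control replicate 1 stood with the transected libraries in this list, at 0.22 against -0.93 and -0.81 in the other controls and 0.26 to 0.67 in transected guts. Without both replicate 1 libraries 7 members rose when adjusted over the list alone, with a median of 1.43. Lymphoid markers did not pass, with 6 of 12 members positive and a median of -0.04 (camera adjusted p = 1.00).

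Genes of antimicrobial and oxidant defence were split. The NADPH oxidase gene nox1 stood at 11.3 ± 2.28 against 3.65 ± 0.482 CPM and cybb, the phagocyte oxidase subunit, at 16.3 ± 5.67 against 6.99 ± 0.256 CPM. Of 25 tested members 15 were positive, with a median log2 fold change of 0.32, against 19 and 0.65 without both replicate 1 libraries. When adjusted over the list alone 6 rose, against 0 over all genes tested in edgeR and 4 in DESeq2. The 6 were nox1 and nos2a (0.00223 each), cybb and itln2 (0.0183 each), itln1 (0.0365), and ncf1 (0.0374). Of these, itln1 and itln2 encode intelectins, lectins that bind microbial sugars. leap2, an antimicrobial peptide gene, fell (0.0365), from 7.58 ± 1.12 to 4.91 ± 0.232 CPM. The list rose by camera (adjusted p = 0.000759, 0.522 with an estimated correlation), and missed the threshold without control replicate 2 (0.0531). Its median level was 0.10, 0.14 and 0.34 in transected replicates 1, 2 and 3 and 0.25, -0.67 and -0.53 in the controls. Control replicate 1 thus lay among the transected libraries. Without both replicate 1 libraries 11 members rose and 2 fell when adjusted over the list alone. Interferon response genes rose by camera at 0.0450 (0.522 with an estimated correlation), with 16 of 20 members positive and a median of 0.31. That call was lost with the replicate block (0.0671), without transected replicate 2 (0.226), transected replicate 3 (0.0863) or control replicate 1 (0.358), and without both replicate 1 libraries (0.0931).

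Some matrix proteases, which remodel tissue, were higher in transected guts. mmp9, a gelatinase gene, was 37.0 ± 6.43 CPM in transected guts and 7.83 ± 3.21 in controls, the collagenase gene mmp13a 9.90 ± 2.69 against 1.55 ± 0.899, and the metalloprotease gene adam8a 14.4 ± 0.58 against 5.43 ± 1.57. These 3 rose when adjusted over the list alone (0.00489 each), against 0 members over all genes tested in edgeR and 4 in DESeq2. The list of matrix proteases and the plasminogen system rose by camera (adjusted p = 0.00146, 0.522 with an estimated correlation and 0.335 with fry), with 18 of 24 members positive and a median of 0.24, which was 0.47 without both replicate 1 libraries. Control replicate 1 lay among the transected libraries in this list, at 0.12 against -0.49 and -0.30 in the other controls and 0.19, 0.06 and 0.11 in transected guts. With the replicate block 4 rose and 1 fell when adjusted over the list alone, and without both replicate 1 libraries 10 rose and 2 fell. Extracellular matrix genes did not pass, with 19 of 33 positive and a median of 0.04 (camera adjusted p = 0.511).

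Cell cycle and replication genes rose as a list, with the smallest camera p of the 35 (adjusted p = 5.15e-13, 0.522 with an estimated correlation). Of 56 tested members 53 were positive, with a median log2 fold change of 0.35. The kinetochore motor gene cenpe stood at 18.1 ± 3.63 against 8.45 ± 2.92 CPM, ube2c, a ubiquitin-conjugating enzyme gene of mitotic exit, at 6.18 ± 0.919 against 2.75 ± 0.635 CPM, and the proliferation marker mki67 at 40.7 ± 1.4 against 27.5 ± 8.7 CPM. In edgeR 0 members passed, alone or over all genes, where 16 were higher at an unadjusted p under 0.05 and 2 passed in DESeq2. With the replicate block 26 members rose when adjusted over the list alone, and without both replicate 1 libraries 24 did, with a median of 0.54. The list's median level was 0.42, 0.12 and 0.21 in transected replicates 1, 2 and 3 and 0.12, -0.64 and -0.17 in the controls, so that control replicate 1 lay level with transected replicate 2. Epidermal markers, which share 0 members with this list, ran alongside it at 0.56, -0.04 and 0.21 against 0.25, -0.46 and -0.21, and control replicate 2 was lowest in both lists and in skeletal muscle. In a comparison made after the values were seen, the level of the cell cycle list correlated over the 6 libraries at 0.938 with epidermal and 0.861 with skeletal muscle markers. With each group's mean taken off the values were 0.918 and 0.987. For hepatocyte markers they were 0.195 over the 6 libraries and 0.965 with group means taken off, and for exocrine pancreas markers -0.299 and -0.918. The cell cycle list thus moved with epidermal and muscle markers, but not with every list of tissue outside the gut. It moved as closely with matrix proteases (0.963, and 0.929 with group means taken off) and, with group means taken off, with Wnt targets (0.969).

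The stress lists went different ways: heat shock and immediate early lists rose, while oxidative stress and hypoxia genes had 24 of 33 members negative and did not pass (camera adjusted p = 0.0632). Without both replicate 1 libraries this list fell (0.000287, 0.478 with an estimated correlation), with 28 negative and a median of -0.27 against -0.13, and 2 members rose and 10 fell when adjusted over the list alone. Heat shock and unfolded protein response (UPR) genes rose by camera (adjusted p = 0.000187, 0.522 with an estimated correlation), with 36 of 43 members positive and a median of 0.20. The chaperone genes hsp70.3 (11.7 ± 4.34 against 3.52 ± 0.44 CPM) and hsp90aa1.2 (32.0 ± 3.27 against 14.5 ± 3.62 CPM) rose when adjusted over the list alone (0.023 each). Over all genes tested 0 members passed in edgeR, and 2 were higher in DESeq2. With the replicate block 4 rose, and without both replicate 1 libraries 2 rose and 2 fell. That list's call was lost without control replicate 1 (0.152). Immediate early and AP-1 genes rose by camera (4.72e-05, 0.522 with an estimated correlation), with 42 of 48 positive and a median of 0.55, which was 0.24 without the replicate 1 libraries, and the call was lost without transected replicate 1 (0.183). In that list socs3a rose when adjusted over the list alone (0.00564), against 0 members over all genes tested in edgeR and 2 in DESeq2. Adjusted over the list alone, 8 members rose with the replicate block and 4 without both replicate 1 libraries. The AP-1 gene junbb stood at 1040 CPM in transected replicate 1, 151 and 104 in the other transected libraries, 235 in control replicate 1, and 49.7 and 67.2 in the other controls. Genes of p53 and apoptosis did not pass, with 16 of 28 positive and a median of 0.04 (camera adjusted p = 0.449), and without both replicate 1 libraries 2 rose and 3 fell when adjusted over the list alone.

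**Figure D2:**
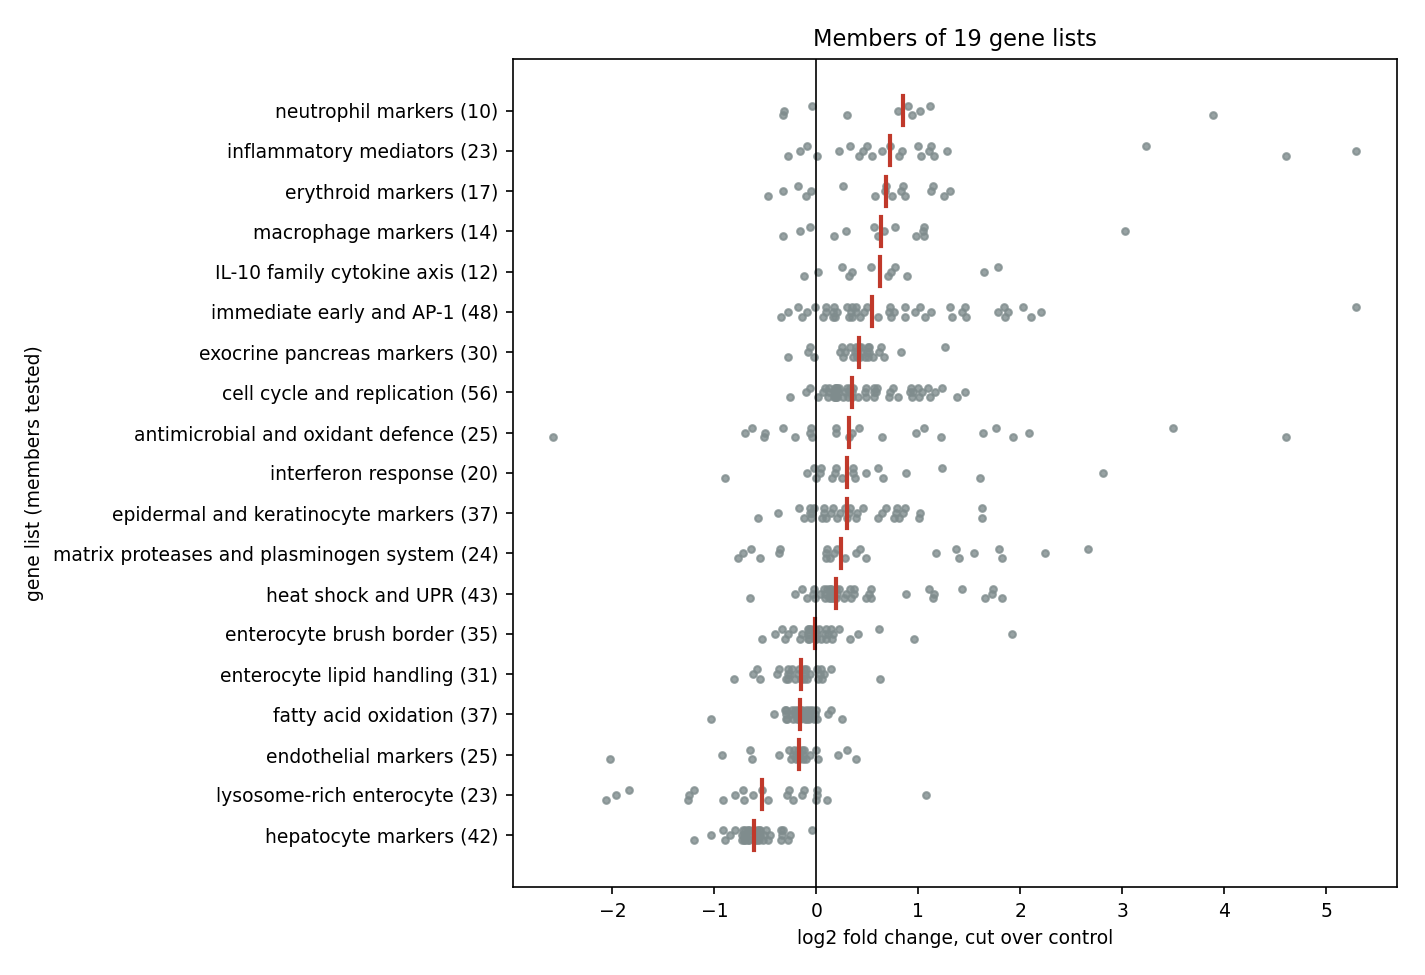
Log2 fold change of transected over control guts for each tested member (grey points) of the 18 lists that camera called and of the enterocyte brush border list, with a red line at each list's median. Medians run from -0.61 for hepatocyte markers to 0.85 for neutrophil markers, and the brush border list lies at -0.01.

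Genes of lysosome-rich enterocytes, the cells of the larval gut that take up and digest luminal protein, fell as a list by camera, though not by stricter tests. ctsl.1, a cathepsin L gene, was 632 ± 469 CPM in transected guts and 2640 ± 532 in controls (log2 fold change -2.06, SE 0.53), ctsbb, a cathepsin B gene, 204 ± 52.3 against 799.9 ± 409 CPM (-1.97, SE 0.46), and lgmn, encoding the protease legumain, 693 ± 85.4 against 1650 ± 651 CPM (-1.25, SE 0.31). The endocytic adaptor gene dab2 stood at 66.7 ± 45.6 against 239 ± 82.6 CPM. Of 23 tested members 19 were negative, with a median log2 fold change of -0.53. When adjusted over the list alone 10 fell: dab2, ctsl.1, ctsbb, ctsh, lgmn, naga, dpep1, glb1 and ctsa at 0.0296 each and ctsz at 0.0329. ctsk, encoding the collagen-degrading cathepsin K, rose in the same list (0.0296), from 19.8 ± 4.4 to 41.8 ± 14.8 CPM. Over all genes tested 0 members passed in edgeR, with 11 lower at an unadjusted p under 0.05 and 6 lower in DESeq2. The camera adjusted p of the list was 7.84e-07 (0.522 with an estimated correlation and 0.335 with fry). Control replicate 1 lay with the transected libraries in this list, at -0.16 against 0.63 and 0.34 in the other controls and -0.12, -0.32 and -0.44 in transected guts. With the replicate block 2 members fell when adjusted over the list alone, and without both replicate 1 libraries 14 did, with a median of -0.92.

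Lists of fat metabolism fell by small amounts. cpt1b, which encodes a carnitine palmitoyltransferase that admits long-chain fatty acids to mitochondria, fell when adjusted over the list alone (0.00259, 0.121 over all genes in edgeR, range over the alternatives 9.76e-08 to 0.713), from 36.0 ± 0.398 to 17.6 ± 2.11 CPM. Of 37 fatty acid oxidation genes tested 33 were negative, with a median of -0.16 (camera adjusted p = 8.45e-05, 0.522 with an estimated correlation), and 10 fell when adjusted over the list alone without both replicate 1 libraries. Of 31 genes of enterocyte lipid handling 23 were negative, with a median of -0.15 (camera 0.00116, 0.140 with an estimated correlation), and 2 fell when adjusted over the list alone with the replicate block, against 0 without it (in edgeR, 2 lower at an unadjusted p under 0.05, 0 in DESeq2). Brush border genes, the transporters and hydrolases of mature enterocytes, did not pass, with 16 of 35 positive, a median of -0.01 and a mean of 0.07 (camera adjusted p = 0.922), although without both replicate 1 libraries 4 rose and 1 fell when adjusted over the list alone.

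Of the neighbouring organs, liver and pancreas markers gave list calls in opposite directions, with overlapping libraries. Hepatocyte markers fell (camera adjusted p = 1.07e-09, 0.522 with an estimated correlation), with 42 of 42 tested members negative and a median log2 fold change of -0.61. The transferrin gene tfa stood at 1070 ± 342 against 2190 ± 1040 CPM and tdo2a, a tryptophan dioxygenase gene, at 103 ± 29.4 against 195 ± 64.2 CPM, each with overlapping groups, and 0 members passed in edgeR, alone or over all genes (6 lower at an unadjusted p under 0.05, 0 in DESeq2). With the replicate block 6 members fell in edgeR when adjusted over the list alone, and tfa and tdo2a passed in DESeq2 (adjusted p = 0.000281 each, with ranges over the alternatives of 0.000281 to 0.997 for both). The list's median level was 0.25, -0.63 and -0.52 in transected replicates 1, 2 and 3 and 0.88, -0.40 and 0.41 in controls, lower in transected guts within each pair. Exocrine pancreas markers rose by camera (0.000194, 0.745 with an estimated correlation), with 26 of 30 positive and a median of 0.42, and the digestive enzyme genes prss59.2 and cela1.6 overlapped between groups. In pair 2 the pancreas list was lower in the transected library, at 0.29 against 0.55. That call was lost without transected replicate 3 (0.0584) or control replicate 1 (0.708).

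Other cell types gave weaker lists. Erythroid markers rose by camera (0.00751, 0.615 with an estimated correlation), with 12 of 17 positive and a median of 0.68 (0.30 without both replicate 1 libraries), and the level in transected replicate 1 was 1.11 against -0.63 to -0.04 elsewhere. The call was lost without transected replicate 1 (0.0708), without control replicate 1 (0.358) and without both (0.533). Endothelial markers fell (0.0078, 0.522 with an estimated correlation), with 21 of 25 negative and a median of -0.17, a call lost without transected replicate 3 (0.134), control replicate 1 (0.117) or both replicate 1 libraries (0.0765). Epidermal and keratinocyte markers rose (0.000366, 0.522 with an estimated correlation), with 28 of 37 positive and a median of 0.30, and missed the threshold without control replicate 2 (0.0543). When adjusted over the list alone 3 members rose with the replicate block and 7 without both replicate 1 libraries, against 0 with all 6 unblocked (in edgeR, 5 higher at an unadjusted p under 0.05, 2 in DESeq2). The replicate 1 libraries stood highest of their groups in this list, at 0.56 in transected and 0.25 in control guts. Skeletal muscle markers did not pass (0.0527), with 17 of 34 positive and a median of 0.01, and 4 members rose with the replicate block when adjusted over the list alone. Without both replicate 1 libraries 24 were positive, with a median of 0.54. Their level ran from -2.0 in control replicate 2 to 1.06 in control replicate 1, and they passed upwards with the replicate block (0.00752), without both replicate 1 libraries (0.00444), and without transected replicate 2 (0.00107), control replicate 1 (5.46e-06) or control replicate 3 (0.0269).

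**Figure D3:**
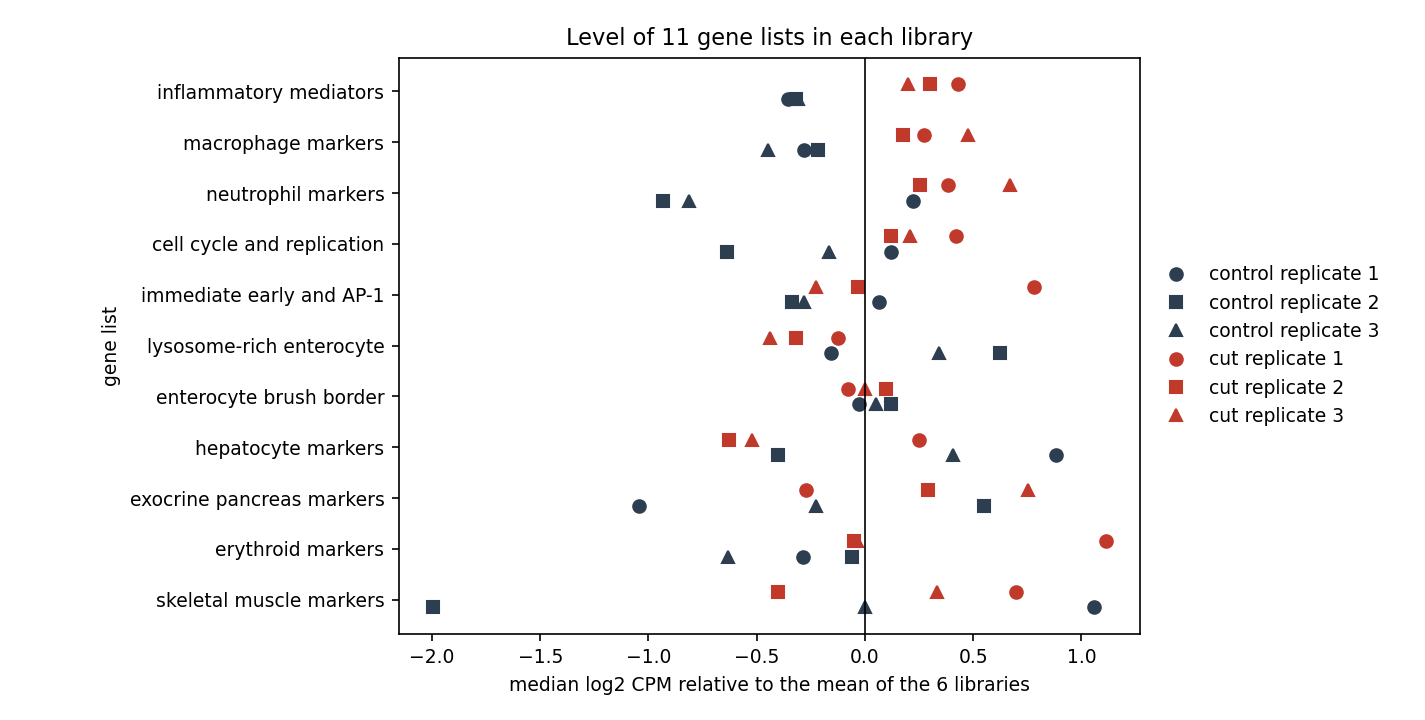
Median level of 11 gene lists in each library, as log2 CPM relative to the mean of the 6 libraries, with colours for group and symbols for replicate number. Inflammatory mediators and macrophage markers separate the groups, while for hepatocyte markers the replicate 1 libraries (0.25 and 0.88) lie high in both groups.

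The remaining lists did not pass with all 6 libraries. Secretory and specialised epithelial types stayed short of the threshold: goblet cell markers had 7 of 11 positive and a median of 0.25 (camera adjusted p = 0.0977), enteroendocrine markers 11 of 32 and -0.16 (0.137), and BEST4/OTOP2 cell markers 3 of 6 and 0.06 (0.720). Progenitor and patterning lists lay near 0 with all 6 libraries, with Notch and progenitor genes at 17 of 26 and 0.10 (0.720), gut patterning regulators at 23 of 42 and 0.03 (0.847, mean -0.04), and Wnt targets at 11 of 23 and -0.02 (0.656, mean 0.02). In the Wnt list rspo3, a Wnt-enhancing R-spondin gene, fell when adjusted over the list alone (0.0473), against 0 over all genes tested and 0 in the list with the replicate block, while without both replicate 1 libraries 2 members rose and 1 fell, rspo3 (0.0486). Enteric neuron and glia markers had 18 of 33 positive and a median of 0.01 (0.486), and smooth muscle markers 11 of 23 and -0.04 (0.720, mean 0.10). Ribosomal proteins had 62 of 70 positive and a median of 0.07 (0.0541), the respiratory chain 38 of 61 and 0.02 (0.847), oxidative stress and hypoxia genes 9 of 33 and -0.13 (0.0632, and 0.0323 downwards with the replicate block), and sterol synthesis genes 5 of 27 and -0.10 (0.264). Single libraries decided some of these: without control replicate 1, calls appeared for enteroendocrine markers (0.00129, down), Wnt targets (0.0113, up), oxidative stress and hypoxia (0.00129, down), sterol synthesis (0.000416, down), ribosomal proteins (0.000225, up) and the respiratory chain (0.00354, down, the reverse of its direction with all 6). Without transected replicate 1 calls appeared for oxidative stress and hypoxia (0.0346) and the respiratory chain (0.0177), without transected replicate 2 for enteroendocrine markers (0.0194) and ribosomal proteins (0.000426), without transected replicate 3 for sterol synthesis (0.0407) and enteric neuron and glia markers (0.0309), and without control replicate 2 for goblet cell markers (0.025), the respiratory chain (0.025) and ribosomal proteins (0.0329). Without both replicate 1 libraries calls appeared for Wnt targets (0.0380, up, with 16 positive, 6 negative and a median of 0.22), sterol synthesis (0.0380, down, -0.15), ribosomal proteins (0.0252, up), oxidative stress and hypoxia (down, as above) and enteric neuron and glia markers (0.0380, down, -0.27, the reverse of their direction with all 6), and the smallest adjusted p of any list with an estimated correlation was then 0.464. Of the lists still short of the threshold then, the median moved to -0.24 for enteroendocrine, 0.12 for goblet cell, -0.18 for BEST4/OTOP2 cell and -0.23 for smooth muscle markers. The camera p-values here use the preset inter-gene correlation of 0.01, which treats the members of a list as nearly independent. The estimated correlation was 0.847 for ribosomal proteins and 0.731 for the respiratory chain. Where libraries were left out, the p-values rest on the remaining ones only.

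Beyond the lists, genes that passed in DESeq2 with and without the replicate block numbered 131, with 79 higher and 52 lower. Among those singled out after their values were seen, lgals1l1, a galectin-like gene, stood at 22.1 ± 9.63 against 0.799 ± 0.44 CPM (log2 fold change 4.76, DESeq2 adjusted p = 1.2e-20, edgeR 0.121, range over the alternatives 3.61e-25 to 0.713). irg1l, an immune-responsive gene, stood at 239 ± 162 against 16.4 ± 6.02 CPM (3.87, DESeq2 adjusted p = 0.000445, range 4.3e-181 to 0.994). The innate immune sensor gene sting1 was 8.57 ± 2.27 against 2.47 ± 0.315 CPM, and the laminin gene lama1 4.82 ± 0.445 against 1.28 ± 0.357 CPM. Among lower genes, the lysosomal mannosidase gene man2b1 was 116 ± 29.6 against 408 ± 179 CPM, tdo2b, a tryptophan dioxygenase gene, 93.0 ± 31.3 against 324 ± 88.5 CPM, and xirp1, which encodes an actin-binding protein of striated muscle, 6.78 ± 2.65 against 23.0 ± 3.55 CPM. For each of these 7 genes the 3 transected libraries lay wholly on one side of the 3 controls. This was a condition for naming lgals1l1, irg1l, man2b1, tdo2b and xirp1, so it adds no support for them.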

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

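The alternatives without the replicate 1 libraries of both groups, DESeq2 with the replicate block, and the block with an estimated correlation or with fry were chosen after the data were seen; the rest were fixed in advance. Where a value below differs, the cause was not tested, except that leaving libraries out leaves fewer samples. The 2 genes higher and 0 lower with all 6 libraries in edgeR became 92 and 60 with DESeq2, 159 and 123 with DESeq2 and the replicate block, 99 and 172 in edgeR without both replicate 1 libraries, and 273 and 404 in DESeq2 without them. With limma-voom 0 were higher and 0 lower (in edgeR, 495 and 407 at an unadjusted p under 0.05), and an adjusted p under 0.01 left 0 higher and 0 lower in edgeR. The replicate block in edgeR gave 3 higher and 1 lower. Leaving out each library in turn gave 0 to 4 higher and 0 to 1 lower. The other scalings, filters, robust fitting off, a 2-fold limit and a test against a 1.5-fold change each gave 2 higher and 0 lower.

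il22 kept its direction in the 18 alternatives, with log2 fold changes of 1.26 to 1.96 when single libraries were left out and 1.62 with the replicate block. It passed in DESeq2 with the block (1.61) and in DESeq2 without both replicate 1 libraries (1.64). il26 lies below the expression filter, so most alternatives give it no value; where it was fitted its log2 fold change was 2.43 without a filter (adjusted p = 0.650), 2.61 in DESeq2, 2.63 in DESeq2 with the block and 2.52 in DESeq2 without the replicate 1 libraries.

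Of the fixed lists, 13 rose and 5 fell, and leaving out each library in turn gave 12 to 14 up and 5 to 8 down. With an estimated correlation 0 rose and 0 fell, with or without the replicate block. fry called 2 up and 1 down, and fry with the block 0 and 0. camera with the block called 13 up and 6 down, sharing 17 lists with the unblocked test, and without both replicate 1 libraries it called 21, sharing 15. The respiratory chain turned downwards and passed without control replicate 1 (adjusted p = 0.00354, with 0.00354 to 0.472 over the libraries left out), and enteric neuron and glia markers turned downwards and passed without both replicate 1 libraries (0.0380). Lists short of the threshold passed with library-size scaling (oxidative stress and hypoxia, 0.04998), with DESeq2 size factors (skeletal muscle markers, 0.0390) and with a filter of CPM at least 1 (ribosomal proteins, 0.0423). Over named genes and alternatives, 1411 values kept their direction and side of the threshold, 246 newly passed, 13 no longer passed and 0 reversed. For lists, 410 values stayed on their side of the threshold, 38 of them short of it with the other sign, 27 newly passed, 86 no longer passed and 2 reversed with a call. Beyond the changes named here and beside each result, the block changed no other call on a list. Depth limits what can be said of il26, il10 and lepb, which had 0 to 2 counts in each control library.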

Other observations

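In this part, the tests of fewer mature enterocytes, fewer lysosome-rich enterocytes, less liver, handling time and carried-over muscle or skin were chosen after the results were seen. The genes named were likewise singled out after their values were seen. plekhs1 has relatives beside it in the RefSeq table of assembly GRCz12tu, where the symbols zgc:153920 and zgc:158404 belong to plekhs1.2 and plekhs1.3. zgc:153920 was also higher in transected guts, at 2.11 ± 0.695 against 0.113 ± 0.0803 CPM (log2 fold change 4.12, SE 0.55), with an adjusted p of 0.149 in edgeR and 4.08e-06 in DESeq2, over a range of 4.08e-06 to 0.824. zgc:158404 was 2.81 ± 1.17 against 1.00 ± 0.886 CPM and passed in 0 alternatives, with adjusted p from 0.0855 to 0.997. How reads were shared between these copies was not analysed here.

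Some further single genes also differed in DESeq2. The gene and1, an actinodin gene of larval fin fibres, stood at 90.4 ± 20.6 against 18.8 ± 13.3 CPM (DESeq2 adjusted p = 0.00538, edgeR 0.468, range 1e-08 to 0.994), and krt17, a keratin gene of the epidermal list, at 178 ± 89.99 against 57.6 ± 21.3 CPM (0.00694, edgeR 0.422, range 7.09e-15 to 0.994). The transcription factor genes sp8a (24.3 ± 5.08 against 10.1 ± 2.49 CPM) and sp9 (7.63 ± 5.07 against 1.49 ± 1.32 CPM) were higher as well. Lower in transected guts were glula, a glutamine synthetase gene (30.7 ± 2.02 against 75.0 ± 17.0 CPM, DESeq2 adjusted p = 2.69e-06, edgeR 0.149), the insulin-regulated transcription factor gene foxo1a (27.8 ± 5.62 against 55.3 ± 15.0 CPM) and the phosphatidate phosphatase gene lpin1 (174 ± 72.8 against 370.4 ± 42.9 CPM). cyp2k6, a cytochrome P450 gene, stood at 6.73 ± 2.65 against 30.5 ± 14.3 CPM.

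Most lysosomal genes were lower in transected guts, with a median log2 fold change of -0.53 in the lysosome-rich enterocyte list. Over 33 genes of the lysosomal lumen the median was -0.37, with 28 negative. Most of these encode hydrolases, though psap and npc2 do not. The 95% intervals in this paragraph are bootstrap intervals of a median over genes (10000 draws), so they hold no spread between libraries. Brush border genes, which mature enterocytes share, had a median of -0.0117 (95% interval -0.0730 to 0.0922), which argues against a lower share of enterocytes as the whole cause, although enterocyte lipid handling genes were lower by a smaller amount, with a median of -0.15 and 23 of 31 negative. A smaller lysosomal compartment stays open, since lysosomal membrane genes were lower too, at -0.242 (95% interval -0.338 to -0.0557). That class also held the transcription factor genes tfeb and tfe3a. Fewer lysosome-rich enterocytes also stay open, with their uptake and region markers at a median of -0.219 (95% interval -0.696 to -0.00177). These 10 markers were mixed, with 8 negative. dab2 (-1.84) and dpep1 (-0.919) were low, while fabp6 (-0.00177, SE 0.53), slc10a2 (0.00406) and snx5 (0.00213) hardly differed. A direct effect of transection on lysosomal genes was not tested. Control replicate 1 lay with the transected libraries here, so the difference rests mostly on pairs 2 and 3.

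Hepatocyte markers were lower in transected guts in 42 of 42 genes tested. Their residuals moved together, with an inter-gene correlation of 0.780, but ribosomal proteins reached 0.847 and the respiratory chain 0.731, so this value does not tell whether less liver was left on the transected guts, which stays open. Of the 42 genes 4 are in another list, and the most abundant by mean, cyp3a65 (8053 to 9153 CPM in transected and 10159 to 12221 in control libraries), is also expressed by the gut. apoa2, an apolipoprotein gene of the liver, stood at 2984, 1691 and 1803 CPM in transected replicates 1, 2 and 3 against 5313, 1845 and 3086 in controls. A change of liver transcription after transection was not tested and stays open.

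The replicate 1 libraries of both groups stood apart from replicates 2 and 3, and the labels give no date or batch. Control replicate 2 stood out at the other end of the first principal component (-48.5). The fits without replicate 1 keep that library as a control. Shared deviation was set against 10000 random lists. Clock genes other than nr1d1 and per1a lay at percentile 100 (median 0.389 against 0.0880), as did skeletal muscle and epidermal genes (0.602 against 0.105). A different time of day and carried-over muscle or skin may therefore each contribute. The random lists were matched on mean expression only, while genes of such sets can move together (estimated correlation 0.741 for skeletal muscle markers). A high percentile thus shows that a set differed in replicate 1, but not why. The 3 most abundant markers each of muscle and epidermis were mixed: gapdh stood at 5058 and 4757 CPM in transected and control replicate 1 against 2912 to 3310 elsewhere, actc1b stood at 2120 and 3106 against 262 to 1809, and krt4 at 1819 and 1416 against 909 to 1326, but eno3 at 1697 and 1809 lay low or within the 1775 to 1946 elsewhere, krt97 at 1662 and 1539 within 1515 to 1698, and krt91 at 1545 and 868 only partly above 646 to 1032. A different handling time stays open, since immediate early and AP-1 genes lay at percentile 96.3 in a test prompted by some of the same genes, and at 88.8 without egr1 and fosab. egr1 (log2 CPM deviations of 5.25 and 4.15 in transected and control replicate 1) and fosab (3.47 and 3.59) were high in both, and the clock genes nr1d1 (-2.62 and -2.55) and per1a (-3.39 and -2.21) were low in both.

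The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. Since the sides of another division are arbitrary, the larger direction was set against the larger of each and the smaller against the smaller. The real division gave 2 genes higher in edgeR, where the highest other gave 0, so that 1 of 10 reached it, while its 0 lower genes leave nothing to compare (495 higher and 407 lower at an unadjusted p under 0.05, 92 and 60 in DESeq2). For lists called by camera the real division gave 13 up, where the highest other gave 12 and 1 of 10 reached it, and 5 down, where the highest other gave 9 and 6 of 10 reached it. Counted over both directions, the real division gave 18 lists, fewer than the 21 of transected replicates 1 and 3 with control replicate 1 and the 19 of transected replicates 1 and 2 with control replicate 1. In DESeq2 the real division gave 152 genes, and transected replicate 1 with control replicates 1 and 3 against the rest gave 262, which points to a structure of the samples other than the groups. The divisions with 21 and 19 lists part the members of 1 pair only. Among the divisions that part the members of all 3 pairs, as the real one does, the others gave 8, 14 and 14 lists by camera. In DESeq2 they gave 0, 0 and 19 genes. There are too few of these for a share under 0.05. Without the replicate 1 libraries the real division gave 271 genes in edgeR, and both other divisions of those 4 libraries gave 0. These 3 divisions are again too few for a share under 0.05, and leaving out replicate 1 was chosen after the data were seen.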
